A study of Homo sapiens with 24 samples.

How the data were processed

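The measurements were poly(A) RNA-seq libraries from HK-2 cells, an immortalised human proximal tubular epithelial line. Per the labels' protocols, cells were serum-deprived overnight and then incubated for 24 h with solvent, with BAY, with TGF-β1 at 2 ng/mL, or with both, in normoxia, and with solvent or BAY in hypoxia at 0.3% oxygen. BAY stands for the BAY compound named in the labels, an activator of soluble guanylate cyclase, the enzyme that makes cyclic GMP in response to nitric oxide. The labels give its final concentration as 1 mM. That dose is doubtful, since it is far above those usual in culture for activators of this enzyme, and a misprint of the unit is possible. No value in the count table bears on it, so the BAY effects below belong to an uncertain dose.

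The authors deposited 1 table of estimated counts per Ensembl gene, with 65180 gene IDs and 24 libraries, and 48.6% of its values above 0 were not whole numbers. Per the submitters' processing notes, the values came from Salmon on GRCh38 (hg38), and DESeq2 was used for the tests. Versions, the annotation release and the way transcripts were summed to genes are not given in the sources used here. Whether the quantification used strand is likewise not given. Salmon divides reads between transcripts that share sequence, so values of paralogs, pseudogenes and genes with parallel IDs can trade reads, and overlapping or antisense genes may not be separated.

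The deposited estimated counts were rounded to whole numbers. Symbols were taken by Ensembl ID from a table of gene names, which held 58919 of the IDs. The other 6261 IDs carried 4.36% of all counts, stayed in the library sizes and tests, and are named by ID. Gene positions come from GENCODE 29 on GRCh38, which may not be the authors' annotation. Totals per library ran from 78862528 to 105571250 counts. At this depth 1 CPM (count per 1e6 counts of the library) corresponds to many reads, and the spread between replicates rather than counting limits most values. All 39 pairs of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom from 5.46 to 48.1. It was 5.72 for TGF-β1 replicates 1 and 2 but 35.4 for replicates 1 and 3, which lie in different subsets (described below). An excess over sampling noise excludes copied libraries but does not show that cultures were independent. Every library was counted as 1 replicate, and the effective number may be smaller. The labels call the replicates biological and do not say what separated them, so p-values measure the spread between these cultures of 1 cell line.

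The series text describes a multifactor design within 2 experiments. The hypoxia experiment was fitted on 14 libraries and the TGF-β1 experiment on 18, and the 8 normoxic libraries without TGF-β1 entered both. In edgeR 4.0.16, libraries were scaled by TMM, genes were kept by filterByExpr (21316 and 21639 genes), and each of 9 comparisons was tested by the robust quasi-likelihood test, 2-sided, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes of the fit, and a gene was called at an adjusted p below 0.05. Each adjusted p printed for a gene is from this test. The words rose and fell are used for called genes only. Fold changes are log2 values with a standard error (SE). The SE was not taken from the fit but computed as the absolute log2 fold change divided by the square root of the F statistic, so it is approximate. Levels are CPM, scaled by TMM within the experiment (over all 24 libraries for markers of other cells), with the SD over libraries.

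Before the data were examined, 32 gene lists were written, of pathways that bear on the treatments and on this cell type and of markers of 5 other cell types. Each list with at least 5 tested genes was tested against all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data, and fry, were run beside it. Members called after adjusting over the list alone were counted as well. With the estimated correlation the camera call held for NF-κB, YAP and p53 targets with BAY in normoxia, for YAP targets in the oxygen by BAY interaction, for cholesterol synthesis with BAY on TGF-β1, for NF-κB, p53 and interferon genes in the fit of BAY adjusted for oxygen, and for cholesterol synthesis in that adjusted for TGF-β1. It held for no list in hypoxia, with BAY in hypoxia, with TGF-β1 or in the TGF-β1 by BAY interaction.

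Genes named in the text follow a rule fixed before the data were examined. For each of 5 main comparisons they are the 8 largest rises and the 8 largest falls among called genes with a symbol that is not a clone or locus name, at least 5 CPM in either group and no overlap between the groups, 5 genes of the cyclic GMP pathway (GUCY1A1, GUCY1A2, GUCY1B1, PRKG1 and PDE5A), and for each list called by camera the 2 called members with the largest change. For interactions and additive fits they are the 4 called genes with the smallest p per direction, under the same conditions on symbol and level. For markers of other cells they are the 2 most abundant members. Exceptions are marked where they stand. Some genes that the rule selects are not reported.

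Alternatives fixed beforehand were RLE in place of TMM, no filter and a stricter filter at 1 CPM, DESeq2 1.42.0, limma voom, the replicate number as a block, all 24 libraries in 1 fit, replicates 1 to 3 only, a 2-fold minimum, and each replicate left out in turn. The libraries of 3 groups (normoxic solvent, TGF-β1, and TGF-β1 with BAY) fell into 2 subsets along a component of their deviations from the group means that held 19.2% of that variance, and each subset was then analysed alone, or the subset was added as a term, as alternatives chosen after seeing the data. The subsets were found from the expression values, and no label names them. They hold none of the hypoxic or BAY-only normoxic libraries, which could not be placed and entered the analysis of either subset whole. The subsets were not compared with each other. Subset 1 holds solvent replicates 1, 2 and 5 and replicates 1 and 2 of both TGF-β1 groups. Apart from solvent replicate 5 the subsets therefore follow the labelled replicate numbers, and a batch that went with these numbers stays open.

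The procedure was tested on simulated counts with known changes. For the hypoxia comparison 96% of the genes changed 2-fold and 58% of those changed 1.25-fold were called in the right direction, over 21144 simulated genes, and 0.0383% of unchanged genes were called. For BAY in hypoxia these shares were 95%, 53% and 0.111%. For the oxygen by BAY interaction they were 87%, 29% and 0.0723%. For BAY with TGF-β1, over 21422 simulated genes, they were 97%, 65% and 0.0809%. The changed genes were drawn from those at 1 CPM or more. In the simulated hypoxia comparison 20914 of the 21144 genes were unchanged, whereas in the data 60.8% of the genes tested were called. Genes were also drawn independently of each other, so library subsets were not simulated. The shares of unchanged genes called are therefore not estimates of false calls in the data.

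Comparisons that share libraries were handled separately. Fold changes with TGF-β1 and with BAY on TGF-β1 share the TGF-β1 libraries, so these were split between them in all 20 ways. For BAY in hypoxia 20 simulations with no BAY effect stand beside the observed value. A split of the 3 hypoxic controls into 1 and 2, in all 6 ways, and a 2-fold minimum with the normoxic controls split between hypoxia and TGF-β1 were added after the data were seen. A lone control is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.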

Results

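RNA from HK-2 cells was profiled in 24 libraries of 6 groups. Normoxic solvent controls, normoxic cells with TGF-β1 and normoxic cells with TGF-β1 and BAY had 5 libraries each. Normoxic cells with BAY, hypoxic solvent controls and hypoxic cells with BAY had 3 each. Totals ranged from 78862528 counts (hypoxia with BAY, replicate 2) to 105571250 (TGF-β1 with BAY, replicate 2). The first principal component held 45.6% of the variance and the second 14.5%. Transcripts encoded by the mitochondrial genome took 7.29% ± 0.174 of the counts in normoxic controls (SD, n = 5), 3.65% ± 0.192 in hypoxic controls (SD, n = 3) and 5.20% ± 0.217 with TGF-β1 (SD, n = 5).

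**Figure D1:**
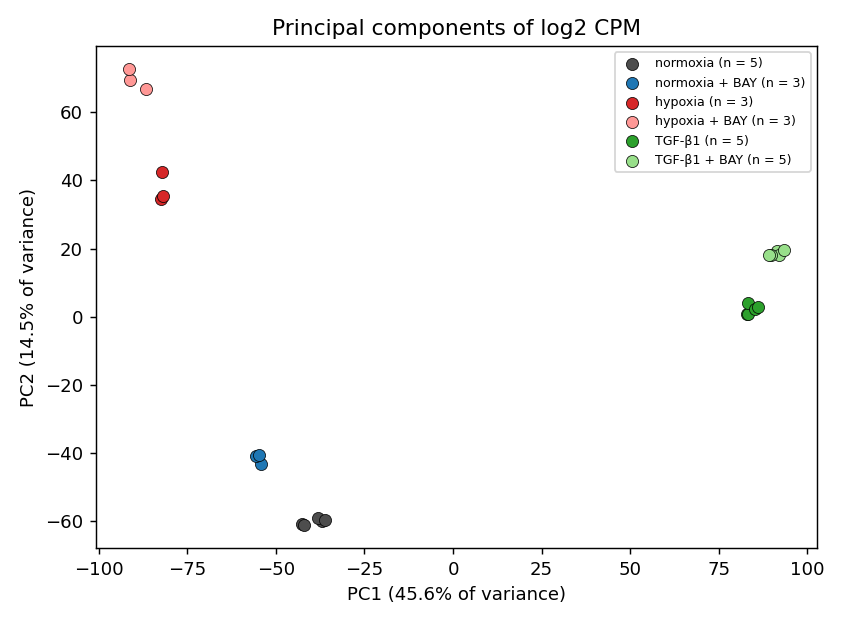
Scores of the 24 libraries on the first (x axis, 45.6% of variance) and second (y axis, 14.5% of variance) principal components of log2 CPM, 1 point per library, coloured by group. Libraries of a group lie together, with TGF-β1 groups at the right, hypoxic groups at the upper left and normoxic groups without TGF-β1 at the lower left.

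Markers of other cell types were measured as a background. The most abundant were the fibroblast markers COL1A1 and LUM at 112 and 90.4 CPM over all libraries, the immune markers CD74 and CD68 at 159 and 132 CPM, and the podocyte marker SYNPO at 261 CPM. PODXL, next among podocyte markers, stood at 4.13 CPM. Of endothelial markers EGFL7 had 36.4 CPM and ERG 1.68 CPM, and of distal nephron markers SCNN1A had 19.1 CPM and AQP3 4.26 CPM. SYNPO was 71.9 ± 10.2 CPM in normoxic controls (SD, n = 5), 457 ± 18.4 in hypoxic controls and 1269 ± 69.4 in hypoxia with BAY (SD, n = 3 each). COL1A1 was 36.0 ± 2.15 CPM in normoxic controls and 228 ± 7.52 CPM with TGF-β1 (SD, n = 5 each).

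The first comparison asked how 24 h of hypoxia changed expression in solvent-treated cells. Targets of the hypoxia-inducible factors rose: 34 of 36 tested members rose, none fell and 2 were not called (35 were called adjusted over the list alone, 34 of them higher), with a median log2 fold change of 2.61. CA9, a carbonic anhydrase, rose from 0.0738 ± 0.0263 to 9.30 ± 0.227 CPM, and ANGPTL4, a lipoprotein lipase inhibitor, from 0.203 ± 0.105 to 8.03 ± 0.462 CPM (SD, n = 5 and 3). Genes of glycolysis rose in 15 of 16 cases and none fell, among them ENO2 by 2.23 and PGK1 by 2.09 on the log2 scale. All 13 mitochondrially encoded genes fell, with a median of -1.52. The camera calls of these lists had adjusted p = 1.21e-22, 1.98e-10 and 2.23e-08, and adjusted p = 0.118, 0.256 and 0.326 with an estimated correlation.

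Among single genes, NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) rose from 250 ± 50.9 to 8709 ± 474 CPM (SD, n = 5 and 3; log2 fold change 5.12, SE 0.139, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.47e-12). KISS1R, the kisspeptin receptor, PDE4C, a cyclic AMP phosphodiesterase, and ADM, which encodes the vasodilator adrenomedullin, rose by 8.31, 4.94 and 4.36 on the log2 scale. TCAF2 rose by 5.14. The antisense RNA HIF1A-AS3 was called 5.65 higher, but without known strand its reads cannot be told apart from those of the overlapping HIF1A. The largest falls included RPS6KL1 (-3.07), TIGAR (-2.96), SLC25A35 (-2.74), OSBPL6 (-2.62) and ADAMTS7 (-2.62). CCN2, a matricellular protein gene, fell by 3.21, with a wide spread among the normoxic controls (71.9 ± 35.3 CPM, SD, n = 5), and its log2 fold change was -2.07 against subset 2 of these controls alone.

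Cytosolic ribosomal protein genes rose in 40 of 41 cases, with a median of 0.56, for example RPS3 from 799 ± 45.7 to 1358 ± 134 CPM (SD, n = 5 and 3). Of 32 proliferation genes 20 fell and 3 rose, with PCNA at -1.83 and UHRF1 at -1.68. Of 22 endoplasmic reticulum chaperone and unfolded protein genes 17 fell and 4 rose, with SDF2L1 at -2.33 and CRELD2 at -1.86. Interferon response genes fell in 16 of 22 cases and rose in 2. Genes of the citric acid cycle fell in 13 of 21 cases and rose in 3, and genes of cholesterol synthesis fell in 12 of 23 and rose in 2, with HMGCS1 at -1.35. NRF2 targets fell in 15 of 23 cases and rose in 5, among them the cystine transporter SLC7A11 at -2.21. With an estimated correlation none of these 7 calls was kept, at adjusted p = 0.568, 0.689, 0.438, 0.141, 0.689, 0.689 and 0.689 in this order. GUCY1A1, GUCY1A2 and GUCY1B1, which encode subunits of the BAY target, were not called (log2 fold changes -0.06, 0.11 and 0.04), but GUCY1A2 was called without hypoxic control replicate 3 (0.20, edgeR adjusted p = 0.0417). In turn PRKG1 and PDE5A fell by 1.07 each, at 0.541 ± 0.113 and 3.10 ± 0.112 CPM in normoxic controls (SD, n = 5).

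In all, 12960 of 21316 genes were called in hypoxia, 6217 higher and 6743 lower, and 2858 of them changed at least 2-fold. Against the normoxic controls of subset 1 alone 13193 genes were called, and against those of subset 2 alone 12265. The labels number the RNA samples 1 to 18 in normoxia, and in hypoxia 21 to 23 with BAY and 31 to 33 with solvent. They do not say what the numbers mark, which in hypoxia also separate BAY from solvent. In normoxia they run by group as well: BAY 1 to 3, solvent 4 to 7 and 18, TGF-β1 8 to 12, and TGF-β1 with BAY 13 to 17. Low oxygen is known to activate the hypoxia-inducible factors, of whose targets 34 of 36 rose, and a difference in handling that went with oxygen stays open for genes with no such known link.

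The second comparison asked what BAY changed in normoxic cells. IL11, a cytokine gene, rose from 2.80 ± 0.302 to 78.9 ± 5.35 CPM, and IGFBP3, an insulin-like growth factor binding protein, from 65.6 ± 1.89 to 611 ± 13.4 CPM (SD, n = 5 and 3). PDK4, which encodes a kinase that inhibits pyruvate dehydrogenase, rose from 12.8 ± 4.13 to 210 ± 3.72 CPM. ANKRD1, a YAP target, fell from 16.5 ± 1.80 to 0.499 ± 0.0491 CPM. Of 21 targets of YAP and TEAD 15 fell and 2 rose, with a median of -1.01. IGFBP3 is also in that list and is 1 of the 2 that rose (3.22 on the log2 scale). Of 24 NF-κB and inflammation genes 19 fell and 2 rose.

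IL11 (ENSG00000095752, chromosome 19, 55364389 to 55370463) had a log2 fold change of 4.82 (SE 0.0788, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.12e-15), and ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276) one of -5.05 (SE 0.138, edgeR adjusted p = 7.93e-13). DNER (5.73), the calcium channel gene CACNA1H (4.07), CSGALNACT1 (3.26), the amino acid transporter SLC38A3 (2.96) and the proteoglycan gene DCN (2.97) also rose. DCN is in the list of fibroblast markers, and LUM of that list rose too, from 80.7 ± 9.85 to 123 ± 3.34 CPM (SD, n = 5 and 3), while COL1A1 was 36.0 ± 2.15 and 35.2 ± 0.582 CPM. TNFRSF9 (-3.50), KIF26B (-2.71) and PLK2 (-2.53) fell. UBD was called 3.51 lower, but a gene ID in parallel to it can share its reads. CCN2, also a target of YAP, fell by 3.06 from 71.9 ± 35.3 CPM in controls, and CCN1, another, fell by 2.53 from 416 ± 148 CPM (SD, n = 5). Against subset 2 alone CCN2 was at -1.95. EGR1 had a log2 fold change of -3.91 with controls at 83.8 ± 70.1 CPM (SD, n = 5), and the call was lost against subset 2 alone (-0.38) and with limma voom (-2.92).

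The YAP, NF-κB and p53 lists were called lower by camera at adjusted p = 8.88e-06, 2.71e-09 and 1.08e-05, and each at adjusted p = 0.0258 with an estimated correlation. Of 22 p53 targets 17 fell and 2 rose, among them GADD45A at -1.85. Against the controls of subsets 1 and 2 alone the median of the YAP list was -1.17 and -0.68, and that of the NF-κB list -1.36 and -1.06. Cholesterol synthesis genes fell in 16 of 23 cases (17 adjusted over the list alone) and none rose (1 adjusted over the list alone), with HMGCS1 at -0.78. Glycolysis genes fell in 11 of 16 cases and none rose, with HK2 at -1.15 and ENO1 at -0.77. Mesenchymal genes fell in 11 of 17 cases and none rose, with the transcription factor SNAI2 at -2.12 and the tropomyosin gene TPM1 at -1.68. The calls of these 3 lists were lost with an estimated correlation, at adjusted p = 0.207, 0.315 and 0.245.

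Of 28 genes of matrix crosslinking and turnover 20 fell and 4 rose, with PLAU at -1.55 and P4HA3 at 1.85. TGF-β and SMAD targets fell in 15 of 26 cases and rose in 5, among them IL11 at 4.82, the largest change of that list. Targets of the hypoxia-inducible factors fell in 22 of 36 cases and rose in 5, with the hormone gene STC2 at -1.99. Integrated stress genes fell in 14 of 25 cases and rose in 3, and interferon response genes fell in 11 of 22 and rose in 3, with IFIT2 at -1.88 and IFIT3 at -1.62. These 5 calls were lost with an estimated correlation, at adjusted p = 0.248, 0.267, 0.423, 0.214 and 0.125. Citric acid cycle genes fell in 11 of 21 cases and rose in 2, and nuclear respiratory chain genes fell in 14 of 44 and rose in 1. Ribosomal protein genes fell in 12 of 41 cases and rose in 1, RPS16, which had the largest change of that list (0.37). Junction genes fell in 16 of 27 cases and rose in 7. Chaperone and unfolded protein genes fell in 11 of 22 and rose in 3, with the rise of CREB3L2 (0.97) as the largest change. With an estimated correlation these 5 had adjusted p = 0.550, 0.715, 0.715, 0.368 and 0.434, and none kept its call. Histone genes rose in 9 of 15 cases and none fell (adjusted p = 0.207 with an estimated correlation). Their transcripts mostly lack poly(A) tails, and near-identical copies can share reads. GUCY1B1 and GUCY1A1 rose by 0.40 and 0.21, and GUCY1A2 and PDE5A fell by 0.38 and 0.63 on the log2 scale. The call of GUCY1A1 was lost against subset 2 alone (0.16). PRKG1 was at 0.02 and not called (edgeR adjusted p = 0.953), and it lay below 0 without BAY replicate 3 (-0.06) or without control replicate 1 (-0.01), 2 (-0.04) or 3 (-0.03).

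In all, 9362 of 21316 genes were called with BAY in normoxia, 4393 higher and 4969 lower, and 1249 changed at least 2-fold. Against controls of subset 1 alone 10507 genes were called, and against those of subset 2 alone 7301.

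The third comparison asked what BAY changed in hypoxic cells. FIBCD1 rose from 0.517 ± 0.0135 to 27.6 ± 2.67 CPM, IL11 from 3.82 ± 0.0559 to 80.9 ± 8.01 CPM and CACNA1H from 7.81 ± 0.242 to 116 ± 8.30 CPM (SD, n = 3 each). The orphan nuclear receptor gene NR4A3 rose by 3.21 on the log2 scale from 0.700 ± 0.195 CPM, and the stress transcription factor gene ATF3 from 8.34 ± 0.629 to 46.6 ± 2.82 CPM. MEF2C, a transcription factor gene, fell from 17.1 ± 1.37 to 4.82 ± 0.364 CPM. Genes of cholesterol synthesis fell in 19 of 23 cases and none rose, with a median of -0.55.

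FIBCD1 (ENSG00000130720, chromosome 9, 130902438 to 130939286) had the largest named rise, with a log2 fold change of 5.73 (SE 0.210, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.06e-11). SLC38A3 (3.40), CSGALNACT1 (3.24), CCN5 (3.14) and the potassium channel gene KCNK15 (3.13) also rose. The fibroblast marker LUM rose from 81.1 ± 3.99 to 185 ± 6.91 CPM, while COL1A1 was 42.7 ± 2.04 and 41.6 ± 2.16 CPM (SD, n = 3 each). PIK3IP1 (-2.13), DOK3 (-2.02), NMRK2 (-1.90), NFE2L3 (-1.78) and the histone deacetylase gene HDAC9 (-1.78) fell. VWA7 and UBD, both with uncertain read assignment, had log2 fold changes of -5.18 and -3.44 (-5.43 with limma voom for UBD in BAY in hypoxia). The call of VWA7 in BAY in hypoxia was lost without hypoxia with BAY replicate 1 (-4.56) or 2 (-4.63), without hypoxic control replicate 1 (-4.44), with limma voom (-7.54) and with a replicate block (-4.84), and its log2 fold change was -12.23 without hypoxia with BAY replicate 3.

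In the cholesterol list SQLE, the squalene epoxidase gene, fell by 0.97. NF-κB and inflammation genes fell in 17 of 24 cases and rose in 3, p53 targets fell in 14 of 22 and rose in 1, and interferon response genes fell in 14 of 22 and rose in 4. IFIH1, a sensor of double-stranded RNA, fell by 1.54. The cyclic AMP and immediate-early list rose in 8 of 18 cases and fell in 1. Mesenchymal genes fell in 8 of 17 cases and rose in 2, with TPM1 at -1.12. Ribosomal protein genes fell in 12 of 41 cases and rose in 1, and mitochondrially encoded genes fell in 6 of 13 and none rose. These 8 lists were called by camera, and none was with an estimated correlation, at adjusted p = 0.0945, 0.0945, 0.0674, 0.113, 0.599, 0.599, 0.986 and 0.742 in this order. GUCY1B1 rose by 0.38 and GUCY1A1 fell by 0.33. PDE5A fell by 0.43, from 1.47 ± 0.164 to 1.10 ± 0.114 CPM (SD, n = 3 each), and its call was lost without hypoxia with BAY replicate 3 (-0.34) or hypoxic control replicate 1 or 2 (-0.38 each), and with no filter on low counts (-0.43). PRKG1 (0.28) and GUCY1A2 (-0.18) were not called, but GUCY1A2 was called without hypoxic control replicate 3 (-0.27, edgeR adjusted p = 0.0274).

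In all, 8087 of 21316 genes were called with BAY in hypoxia, 3524 higher and 4563 lower, and 1082 changed at least 2-fold.

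The effect of BAY in hypoxia was then compared with that in normoxia by their interaction. SLC7A5, a subunit of an amino acid transporter, was 75.8 ± 1.31 CPM in normoxic controls (SD, n = 5) and 69.2 ± 1.52 with BAY, against 166 ± 6.09 and 597 ± 37.5 CPM in hypoxia (SD, n = 3 each). Its interaction was 1.98 (SE 0.0608, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.35e-11). SLC39A14 (1.26), RIMKLB (1.36) and the phosphofructokinase gene PFKP (0.88) also had a more positive BAY effect in hypoxia. FLRT3 (-1.45), LRRC75B (-1.05), the tissue factor gene F3 (-0.84) and the carboxypeptidase gene CPM (-0.64) had a less positive one. For F3 the levels were 105 ± 2.73 (SD, n = 5) and 193 ± 3.32 CPM in normoxia, and 410 ± 7.55 and 421 ± 18.6 CPM in hypoxia (SD, n = 3 each).

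Of 21 YAP and TEAD targets 14 had a more positive BAY effect in hypoxia and 2 a less positive one (adjusted p = 1.43e-07 by camera and 0.0197 with an estimated correlation). A more positive effect can be a smaller fall from a lower start. ANKRD1 went from 16.5 ± 1.80 (SD, n = 5) to 0.499 ± 0.0491 CPM in normoxia, and from 4.04 ± 0.391 to 0.599 ± 0.0953 CPM in hypoxia (SD, n = 3 each). Starting levels were not tested as a cause. Glycolysis genes were more positive in 9 of 16 cases and less in none, and cholesterol synthesis genes were less positive in 9 of 23 and more in none (adjusted p = 0.197 and 0.246 with an estimated correlation). In all 3571 genes were called, 1882 with a more positive and 1689 with a less positive BAY effect in hypoxia, and 5821 were called with the controls of subset 1 alone.

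With oxygen as an additive factor, the receptor gene P2RY6, the autophagy gene GABARAPL1, IL11 and TMEM245 had the smallest p among genes higher with BAY, at 2.72, 2.10, 4.64 and 1.68. NFE2L3 (-1.70), BIRC3 (-1.44), BCAT1 (-1.34) and LRRN4 (-1.54) had the smallest p among lower genes. P2RY6 rose from 11.9 ± 0.802 (SD, n = 5) to 74.9 ± 1.38 CPM in normoxia and from 11.3 ± 0.659 to 78.5 ± 1.13 CPM in hypoxia (SD, n = 3 each). With all 24 libraries in 1 fit the value of P2RY6 was 1.65. NF-κB genes fell in 18 of 24 cases and rose in 2, p53 targets fell in 18 of 22 and rose in 2, and interferon response genes fell in 14 of 22 and rose in 4 (adjusted p = 0.0487, 0.0206 and 0.0487 with an estimated correlation). This fit called 9770 genes, 4479 higher and 5291 lower.

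The next comparison asked what TGF-β1 changed in normoxia. Its known SMAD targets rose in 21 of 26 cases and fell in 1, with a median of 1.18. Among them IL11 rose from 2.73 ± 0.328 to 312 ± 18.8 CPM (SD, n = 5 each). Matrix metalloproteinase genes MMP1 and MMP13 rose by 7.38 and 7.25, and MMP1 reached 673 ± 71.2 CPM from 4.05 ± 0.784. Genes of proximal tubule identity fell in 23 of 30 cases and rose in 4, and the tight junction genes CLDN3 and OCLN fell by 3.34 and 2.92.

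IL7R (ENSG00000168685, chromosome 5, 35852695 to 35879603), an interleukin receptor gene, rose by 7.19 (SE 0.104, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.95e-19), from 0.375 ± 0.0787 to 55.1 ± 2.55 CPM (SD, n = 5 each). LEFTY2 (8.72) and CH25H (8.18) rose as well. CGB8 and CGB5, of the chorionic gonadotropin family, were called higher, but they are near-identical copies that share reads. CGB8 went from 0.00781 ± 0.0175 to 25.3 ± 2.47 CPM (SD, n = 5 each), with 4 of the 5 controls at 0. The gap junction gene GJB1 (-5.29), LGALS2 (-5.26), the transporter genes SLC17A3 (-5.20) and SLC2A2 (-4.60), NMRK2 (-5.03), DDC (-4.88), ARHGEF38 (-4.74) and DEPTOR (-4.71) fell.

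Genes of matrix crosslinking and turnover rose in 25 of 29 cases and fell in 3, collagens and other matrix genes rose in 21 of 32 and fell in 10, and mesenchymal genes rose in 14 of 18 (15 adjusted over the list alone) and none fell. TNC rose by 3.04, SNAI1 by 3.44 and CNN1 by 3.36. Of 7 tested fibroblast markers 3 rose (COL1A1, PDGFRB and FAP), 2 fell (LUM and THY1) and 2 were not called, and the list, with a median of -0.48 and a mean of 0.60, was not called by camera (adjusted p = 0.342). PDGFRB went from 1.39 ± 0.189 to 10.8 ± 0.381 CPM, FAP from 0.0386 ± 0.0219 to 0.400 ± 0.0400 CPM and LUM from 80.7 ± 9.85 to 59.7 ± 5.81 CPM (SD, n = 5 each). PDGFRB, FAP and THY1 were chosen after their values were seen. Proliferation genes rose in 28 of 32 cases and fell in 2, with BUB1B at 1.10 and CDC6 at 0.99. Chaperone and unfolded protein genes rose in 19 of 22 cases and fell in 2, with MANF at 1.39. Glycolysis genes rose in 11 of 16 cases and fell in 2, and hypoxia-inducible factor targets rose in 23 of 36 and fell in 5, with LOX at 3.94. The 7 lists of matrix crosslinking, collagens, mesenchymal, proliferation, chaperone, glycolysis and hypoxia-inducible factor genes, and the SMAD targets, were called higher by camera, and lost the call with an estimated correlation, at adjusted p = 0.418, 0.584, 0.247, 0.247, 0.299, 0.584, 0.793 and 0.0937 in this order.

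Junction genes fell in 19 of 27 cases and rose in 6, interferon response genes fell in 20 of 22 and rose in 1, and tubular injury genes fell in 16 of 20 and rose in 4. YAP and TEAD targets fell in 15 of 21 cases and rose in 3, with AMOTL2 at -2.70 and NT5E at 4.01. In the interferon list EPSTI1 fell by 2.33, and in the tubular injury list ITGB8 fell by 3.26. AQP1, in the proximal tubule list, rose by 5.98 to 1.52 ± 0.287 CPM. Mitochondrially encoded genes fell in 12 of 13 cases, with MT-CO1 at -0.43. These 5 lists and the proximal tubule list lost the camera call with an estimated correlation, at adjusted p = 0.533, 0.247, 0.533, 0.418, 0.584 and, for the proximal tubule list, 0.247. GUCY1A1 fell by 1.37, GUCY1B1 by 0.31 and PRKG1 from 0.528 ± 0.113 to 0.222 ± 0.0935 CPM (SD, n = 5 each), while GUCY1A2 rose by 1.08 and PDE5A was not called (0.14), except within subset 1 (0.27). In all, 13422 of 21639 genes were called with TGF-β1, 6380 higher and 7042 lower, and 3674 changed at least 2-fold.

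The next comparison asked what BAY changed in cells that also received TGF-β1. Cholesterol synthesis genes fell in 20 of 23 cases and rose in 1, with a median of -0.49 (adjusted p = 3.53e-16 by camera and 0.0053 with an estimated correlation). HMGCS1 fell from 190 ± 4.00 to 103 ± 5.26 CPM (SD, n = 5 each). IGFBP3 rose from 50.4 ± 5.48 to 527 ± 87.6 CPM, PDK4 by 4.35 on the log2 scale from 1.95 ± 0.523 CPM, and the hormone gene STC1 from 1.66 ± 0.584 to 25.6 ± 1.63 CPM. ANKRD1 fell from 6.47 ± 0.637 to 0.851 ± 0.137 CPM.

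IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874) had a log2 fold change of 3.39 (SE 0.101, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.24e-13). CHL1 (7.63), NCKAP5 (2.85), KANK4 (2.47), IGFN1 (2.47) and CCN5 (2.45) rose too. HDAC9 (-2.65), MEGF10 (-1.82), DACT1 (-1.70), ANXA3 (-1.68), the transporter gene SLCO4C1 (-1.58), BIRC3 (-1.58) and AKAP12 (-1.56) fell.

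Interferon response genes fell in 13 of 22 cases (15 adjusted over the list alone) and rose in 1 (3 adjusted over the list alone), with IFIT3 at -1.33, and junction genes fell in 15 of 27 and rose in 3, with CGN at -1.07. NF-κB and inflammation genes fell in 12 of 25 cases and rose in 5. The cyclic AMP and immediate-early list rose in 8 of 18 cases and fell in 1, with FOSB at 2.01 and DUSP1 at 1.94, and histone genes rose in 8 of 15 and none fell. NRF2 targets fell in 10 of 23 cases and rose in 1. That rise, of SLC7A11 (1.496), was the largest change among called members of the list, and HMOX1 was at -0.93. Chaperone genes fell in 11 of 22 cases and rose in 2. The camera calls of these lists were lost with an estimated correlation, at adjusted p = 0.557 for interferon genes and 0.873 for each of the other 6. TGF-β and SMAD targets rose in 8 of 26 cases and fell in 7, and were not called as a list (adjusted p = 0.990 by camera). GUCY1A1 fell by 0.60 and PDE5A rose by 0.43. The call of PDE5A was lost with replicates 1 to 3 only (0.35) and within subset 1 (0.16). GUCY1A2 (0.02), GUCY1B1 (-0.07) and PRKG1 (-0.45) were not called, but GUCY1B1 was with RLE or DESeq2 (-0.08 each), with the subset as a term (-0.07) and within subset 2 (-0.10). GUCY1A2 in BAY with TGFB1 lay below 0 without TGF-β1 replicate 1 or 2 (-0.05 each), without TGF-β1 with BAY replicate 3 (-0.03) or 4 (-4.44e-05), and within subset 2 (-0.12), and was called higher within subset 1 (0.27). In all, 6386 of 21639 genes were called, 3012 higher and 3374 lower, and 627 changed at least 2-fold.

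**Figure D2:**
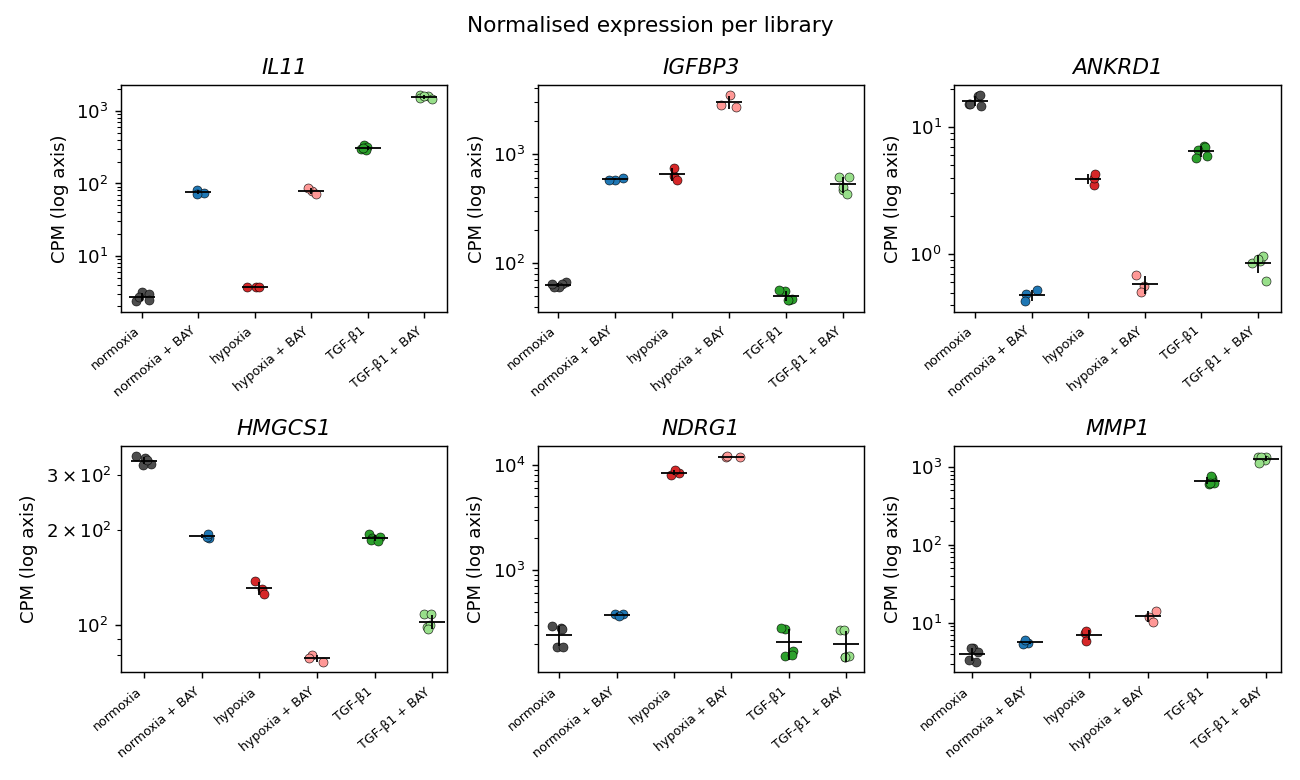
Expression of 6 genes, chosen from the named genes after their values were seen, as CPM on a log axis in the 6 groups, scaled over all 24 libraries together. Points are libraries, horizontal marks are means and vertical bars the SD (n = 5, 3, 3, 3, 5 and 5 from left to right), and IL11, IGFBP3 and ANKRD1 differ with BAY in each of the 3 settings.

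The effect of BAY with TGF-β1 was compared with that in normoxia without it. DKK3, a secreted Wnt pathway regulator, was 107 ± 2.64 CPM in controls (SD, n = 5) and 23.9 ± 0.293 with BAY (SD, n = 3), against 116 ± 1.82 and 96.8 ± 4.75 CPM with TGF-β1 (SD, n = 5 each). Its interaction was 1.91 (SE 0.0472, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.63e-15). TNFRSF12A (1.96), STC2 (2.04) and TGFB2 (2.34) also had a more positive BAY effect with TGF-β1. P2RY6 (-2.57), IL11 (-2.46), STARD13 (-1.95) and RRM2 (-1.80), a ribonucleotide reductase subunit gene, had a less positive one. RRM2 was 181 ± 16.6 (SD, n = 5) and 717 ± 14.2 CPM (SD, n = 3) without TGF-β1, and 210 ± 4.06 and 239 ± 8.86 CPM with it (SD, n = 5 each). IL11 rose in both settings and reached 1577 ± 78.3 CPM with both agents (SD, n = 5).

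Of 21 YAP and TEAD targets 12 had a more positive BAY effect with TGF-β1 and 1 a less positive one, and of 25 NF-κB genes 15 and 1 (adjusted p = 0.481 and 0.612 with an estimated correlation). In all 4487 genes were called, 2956 more positive and 1531 less positive, and 7100 were called with the libraries of subset 1 beside the same 3 BAY libraries without TGF-β1. With TGF-β1 as an additive factor IGFBP3 (3.31), CREM (1.48), AREG (1.33) and CREB3L2 (0.93) had the smallest p among genes higher with BAY. VEGFC (-1.32), ANXA3 (-1.69), CGN (-1.06) and DHCR7 (-0.67) had the smallest among lower genes. VEGFC fell from 23.3 ± 0.705 (SD, n = 5) to 10.0 ± 0.364 CPM (SD, n = 3) without TGF-β1 and from 83.7 ± 1.36 to 32.0 ± 1.21 CPM with it (SD, n = 5 each). Cholesterol synthesis genes fell in 19 of 23 cases (20 adjusted over the list alone) and rose in 1 (adjusted p = 0.0475 with an estimated correlation). This fit called 8576 genes, 3842 higher and 4734 lower.

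**Figure D3:**
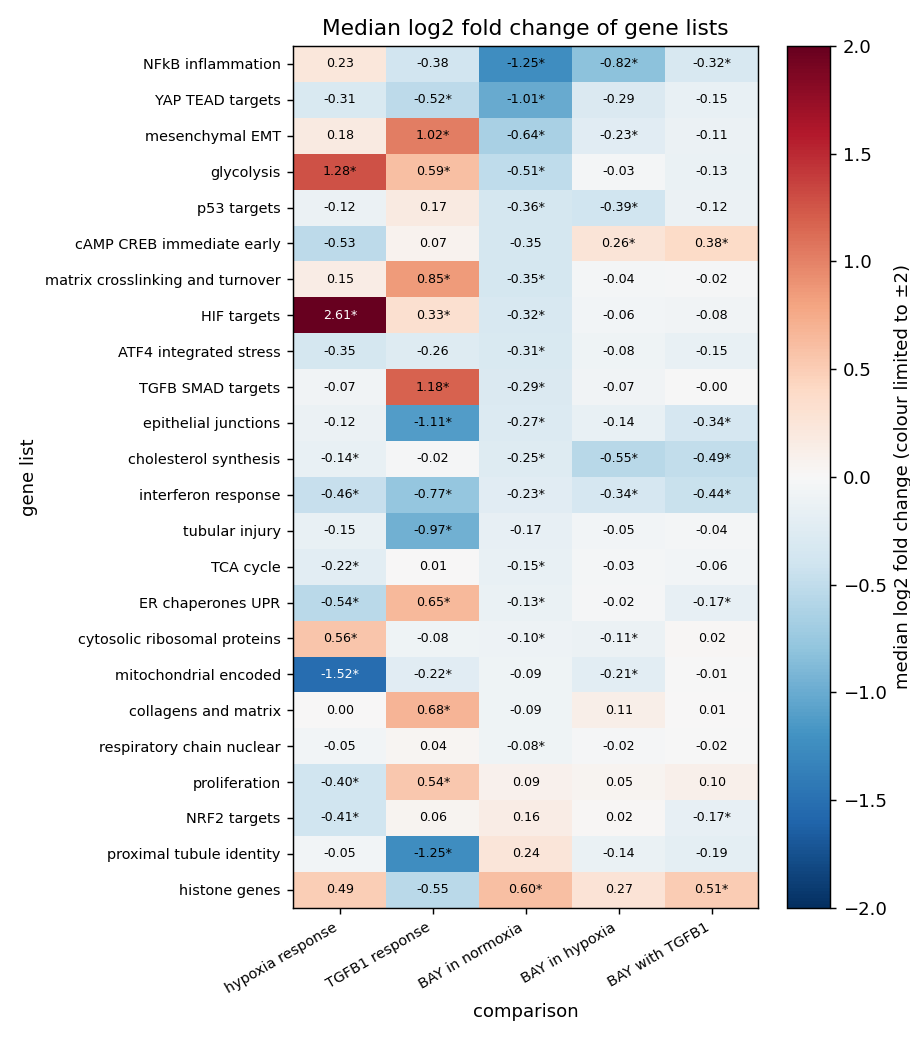
Median log2 fold change (colour and printed value) of the 24 gene lists (y axis) that camera called in any of the 5 main comparisons (x axis). Stars mark a camera adjusted p below 0.05 with the preset correlation, and cholesterol synthesis has one in each of the 3 BAY columns (adjusted p = 0.207 in normoxia, 0.0945 in hypoxia and 0.0053 with TGF-β1 with an estimated correlation).

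Whether BAY moved genes against the TGF-β1 response was measured across genes called with TGF-β1. With the TGF-β1 libraries split so that none entered both fold changes, the slope of the BAY effect on the TGF-β1 effect had a median of 0.055 over 20 splits (0.039 to 0.083), with a median Pearson r of 0.16 across genes, which are not independent replicates. A median of 49.2% of the genes had opposite signs. For genes called in hypoxia, the slope of the BAY effect in hypoxia on the hypoxia effect was 0.033, against a mean of -0.088 (SD 0.0084) in 20 simulations with no BAY effect, and it was -0.062 across all genes tested, against -0.131 in the simulations. With the 3 hypoxic controls split 1 and 2 between the fold changes, the slope among called genes had a median of 0.083 over 6 splits (0.048 to 0.107), with a median Pearson r of 0.16 across genes and 39.2% of the genes with opposite signs, and across all genes tested a median of 0.060 (0.0094 to 0.071).

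Hypoxia and TGF-β1 were compared through the genes called in both, 4069 with the same sign and 5098 with opposite signs. Among 20928 genes tested in both, independent lists give 1736 higher, 2267 lower and 3969 opposite, and 1738 and 2331 were observed higher and lower. Simulations with no effect against the same controls gave 0 shared calls with edgeR, where independent lists give 0 as well. With no changed genes they cannot show what shared controls add to the overlap when many genes change. The covariance of the fold changes was 0.112 against 0.0649 in these simulations (r 0.132 against 0.432). With the controls split between the responses a median of 3318 genes had the same sign and 4330 opposite signs, and the covariance was 0.0365 (-0.0165 to 0.0730). Among genes changed at least 2-fold in both, 183 were higher, 327 lower and 283 opposite, where independent lists give 63.25, 153 and 208. With the controls split, medians of 171 higher, 252 lower and 280 opposite stood against 67.4, 127 and 197, so the share with the same sign depends on the minimum change.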

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

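The tests of gene length and of TRIM27 were chosen before their results were seen, while the bound on mitochondrial transcripts, the tests of the YAP list, the counts of other splits, the margin set on the length test and its version without other ribosomal proteins were chosen after.

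YAP and TEAD targets fell with BAY in normoxia. Against the controls of the subset with the smaller fall the median was -0.681 and 15 of 21 members fell, which argues against the control subsets as the whole cause. The BAY libraries themselves could not be placed in a subset, so a difference of that kind between them and the controls stays open. A response to BAY whatever the other treatment may be a candidate explanation, and camera did not call the list in either of the other BAY comparisons (larger adjusted p = 0.176), which leaves it open. The BAY effect on this list differed between hypoxia and normoxia by the interaction (adjusted p = 0.0197 with an estimated correlation). Members such as ANKRD1 also started lower in hypoxia, and starting levels were not tested as a cause.

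Of 41 ribosomal protein genes 40 rose in hypoxia, and the call of the list was lost with an estimated correlation (adjusted p = 0.568). The fall of the mitochondrial share of the counts would raise every other gene by at most 0.060 on the log2 scale between any hypoxic and normoxic control, even without scaling, which argues against it as the cause of a median of 0.56 (a test chosen first, removing the 37 mitochondrial genes before scaling, moved other genes by a median of 3.3e-05 and decides nothing). Gene length could contribute: 123 genes matched on length and expression had a median of 0.241, and this lies below the bound of 0.28 (which is 0.56 divided by 2) by less than its bootstrap SD of 0.11. Of these, 16 were other ribosomal protein genes, and without them the median was 0.0854 (bootstrap SD 0.092). Length therefore cannot be told apart by the test as set, and handling that went with oxygen was not tested.

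TRIM27 had a log2 fold change of -4.18 in hypoxia, with values from 2.80 to 40.3 CPM among normoxic controls (n = 5). Reads shared with a parallel gene ID may add to the spread within groups. The within-group SD of log2 CPM was 1.68 for TRIM27 and 1.12 for the sum with that ID. The bound set beforehand, 1.68 divided by 2, was not reached, so the test decides nothing on the spread. The sum was 26.7 ± 13.7 CPM in normoxic controls (SD, n = 5) and 0.736 ± 0.478 in hypoxic ones (SD, n = 3). Reads traded between these 2 IDs would leave the sum unchanged, which argues against trading between them as the cause of the lower values in hypoxia. Reads given to any other gene ID were not counted, so read assignment beyond these 2 IDs stays open. The call of TRIM27 in hypoxia response was lost with limma voom (-3.88), against subset 2 alone (-2.86), and without hypoxic control replicate 1 (-4.25) or 2 (-3.73). No biological explanation was tested.

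In groups of 5, a library stood apart from the rest in 9 of 299 sets of values (3.01%), where chance gives about 1 in 20. The gap to the nearest library, as a share of the range, was 0.886 for ADAMTS7 in normoxic control 3 and 1.00 for CGB8 in control 1. In control 5 it was 0.867 for AQP1, 0.743 for CREB3L2, 0.895 for TIGAR and 0.846 for TRIM27. With TGF-β1 it was 0.811 for OCLN in TGF-β1 replicate 2, 0.747 for CREB3L2 in TGF-β1 with BAY replicate 5 and 0.766 for TGFB2 in TGF-β1 with BAY replicate 3.

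The BAY effect differed between hypoxia and normoxia for 3571 genes by the interaction test. Among the named genes the differences were 1.978 for SLC7A5, 1.264 for SLC39A14, 1.357 for RIMKLB, 0.8849 for PFKP, -0.8406 for F3, -1.445 for FLRT3, -0.6359 for CPM and -1.049 for LRRC75B. Of 100 splits of the same libraries 6 called as many genes, the real one included, and the highest other split called 10715. Each of the 5 others kept all or most of the BAY libraries of 1 oxygen level in place and 0 or 1 of the 3 of the other level. Their contrast therefore holds the BAY effect itself, which is a structure of the samples, and this count decides nothing about chance.

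The BAY effect differed with and without TGF-β1 for 4487 genes. The named differences were 1.91 for DKK3, 1.958 for TNFRSF12A, 2.039 for STC2, 2.341 for TGFB2, -1.946 for STARD13, -2.459 for IL11, -2.567 for P2RY6 and -1.80 for RRM2. Of 100 splits 2 called as many genes, the real one included, but these splits mix the BAY effect into the contrast and the groups as those above do, so this count decides nothing about chance either. The other, with 5992 genes, parted normoxic solvent replicates 1, 2 and 5 from the other normoxic libraries and grouped mostly subset 2 libraries with TGF-β1, and with the solvent and TGF-β1 libraries of subset 1 or 2 alone, beside the same 3 unplaced BAY libraries, the real comparison called 7100 and 5142 genes.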

How the results depend on the processing

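The alternatives that use the library subsets, the comparison of pairs within them, the split of the hypoxic controls and the 2-fold minimum with split controls were chosen after the data were seen, and all other alternatives were fixed before. Named genes had 4661 values under the alternatives. In 4615 the direction and the side of the threshold were those reported, in 27 a call was lost, in 8 one was gained and in 11 the direction turned. Both genes that turned lay close to 0. PRKG1 in BAY in normoxia was -0.0002613 with all 24 libraries in 1 fit and -0.03355 against subset 1, and ranged from -0.06137 to 0.143 with single libraries left out. GUCY1A2 in BAY with TGFB1 was -0.124 within subset 2 and ranged from -0.04806 to 0.093 with single libraries left out. The cause was not tested.

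A 2-fold minimum lowered every count of calls by construction, to 2858 in hypoxia, 1082 and 1249 with BAY in hypoxia and normoxia, 415 for the oxygen by BAY interaction, 1042 for BAY adjusted for oxygen, 3674 with TGF-β1, 627 with BAY on TGF-β1, 680 for the TGF-β1 by BAY interaction and 735 for BAY adjusted for TGF-β1. It lowered the genes shared in direction by hypoxia and TGF-β1 from 4069 to 510, or to 423 with the controls split. With the libraries of subset 1, beside the unplaced ones, the interactions rose to 5821 (oxygen) and 7100 (TGF-β1) genes, and the cause was not tested. All other alternatives left each count of called genes within 1.5 times the reported one.

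Leaving out single libraries gave 11985 to 12885 genes in hypoxia, 6879 to 7520 with BAY in hypoxia, 7663 to 9567 with BAY in normoxia, 2561 to 3914 for the oxygen interaction, 8825 to 9713 for BAY adjusted for oxygen, 12986 to 13148 with TGF-β1, 5724 to 6132 with BAY on TGF-β1, 3587 to 4717 for the TGF-β1 interaction and 7738 to 8702 for BAY adjusted for TGF-β1. With the replicate number as a replicate block 12182, 7864, 8379, 3038, 8586, 13911, 7231, 5922 and 8930 genes were called in the same order. Of 51 same-numbered pairs of libraries from different groups 6 had deviations from the group mean correlated above 0.1 across genes, all of them among the 13 such pairs within a subset (mean 0.113, lowest 0.0668). The 24 differently numbered pairs within a subset had a mean of 0.105 and 13 above 0.1. Within a subset the numbers were therefore not taken to pair samples. The hypoxic groups lie outside the subsets. Their 3 same-numbered pairs of BAY and solvent libraries had correlations of 0.0542 to 0.0855 (mean 0.0751). Differently numbered ones had a mean of -0.0375, which follows from the former because deviations sum to 0 in each group, and adds no separate evidence. A pairing there stays open, and the main test of BAY in hypoxia did not use it, while the replicate block gave 7864 genes. With the subset as a term 14383 genes were called with TGF-β1 and 8748 with BAY on TGF-β1, and since the term comes from the same values these p-values are too small.

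The lists called by camera numbered 10 in hypoxia, 8 and 17 with BAY in hypoxia and normoxia, 14 with TGF-β1 and 8 with BAY on TGF-β1. With an estimated correlation they numbered 0, 0, 3, 0 and 1, since correlated members raise the variance of a list. By fry, which does not compare a list with other genes, they numbered 23, 16, 24, 22 and 13. The slope of BAY on TGF-β1 effects was 0.0328 across all genes and 0.0255 without splitting the shared libraries, against 0.0551. That of BAY on hypoxia effects was -0.0624 across all genes and 0.0332 among called genes. The shared hypoxic controls alone gave means of -0.131 and -0.088 in simulations with no BAY effect, so both slopes lie above these values. With the hypoxic controls split they were 0.08283 among called genes and 0.06038 across all genes, so the negative value comes from the shared controls.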

Other observations

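The test of a response common to the 3 BAY comparisons and the counts of other splits were chosen after the results were seen. The 3 BAY comparisons share no library, and 1049 genes were called higher and 1606 lower in all of them. The genes below were chosen from these after their values were seen, and their log2 fold changes are given in normoxia, in hypoxia and with TGF-β1 in this order. Higher genes included PAPPA, which encodes a protease of insulin-like growth factor binding proteins (2.39, 2.79 and 1.75), the binding protein gene IGFBP3 (3.22, 2.18 and 3.39), IGFN1 (2.27, 2.79 and 2.46) and CCN5, a matricellular protein gene (2.89, 3.14 and 2.45). PDE3A, which encodes a phosphodiesterase inhibited by cyclic GMP (2.82, 2.56 and 3.27), was higher too. Lower genes included ANKRD1 (-5.05, -2.75 and -2.92), the histone deacetylase gene HDAC9 (-2.27, -1.78 and -2.65) and MEGF10 (-2.13, -1.90 and -1.82).

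In all, 2655 genes were called in 1 direction in the 3 BAY comparisons, where independent lists of the same sizes give 102.5 higher and 172.4 lower among the 20928 genes tested in each. A response to BAY common to the 3 settings is a hypothesis consistent with this number. A handling step shared by all libraries with BAY was not tested. In pairs of comparisons, 5071 genes had the same sign and 355 opposite signs in normoxia and hypoxia, 3793 and 490 in normoxia and with TGF-β1, and 3299 and 524 in hypoxia and with TGF-β1.

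Camera called 15 lists in the oxygen interaction and 14 in the TGF-β1 interaction, 12 and 11 of them towards a more positive BAY effect under hypoxia or TGF-β1. With an estimated correlation 1 call (YAP and TEAD targets) was kept in the former and 0 in the latter. In the oxygen interaction genes of matrix crosslinking and turnover were more positive in 12 of 28 cases and less in none, and TGF-β and SMAD targets in 12 of 26 and less in 4 (adjusted p = 0.172 and 0.161 with an estimated correlation). In the TGF-β1 interaction p53 targets were more positive in 9 of 22 cases and less in none, and NRF2 targets less positive in 11 of 23 and more in 1 (adjusted p = 0.669 each with an estimated correlation). The cyclic AMP and immediate-early list moved with the control subsets: its median with BAY in normoxia was -0.326 against controls of subset 1 and 0.374 against those of subset 2, and its median in hypoxia was -0.710 and 0.0945. The immune marker CSF1R stood at 13.5 ± 0.927 CPM in normoxic controls and 56.3 ± 3.15 with TGF-β1 (SD, n = 5 each), while PTPRC, which all leukocytes express, had 0.0224 CPM over all libraries.

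Other splits of the same libraries into groups of the same sizes called fewer genes than the real one in 6 comparisons with enough splits for a share under 0.05. Such counts treat libraries as exchangeable, which the subsets go against. The hypoxic and BAY-only normoxic libraries could not be placed in a subset. The splits therefore cannot exclude that treatment went along with a structure of that kind. In hypoxia 1 of 56 splits, the real one, called 12960 genes and the highest other called 2786. With BAY in normoxia 1 of 56 called 9362 and the highest other 4794. In both, that other split parted normoxic controls 1, 2 and 5 from the remaining libraries, as the subsets do. For BAY adjusted for oxygen 1 of 100 called 9770 (highest other 3861), with TGF-β1 1 of 100 called 13422 (2610), with BAY on TGF-β1 1 of 100 called 6386 (1011), and for BAY adjusted for TGF-β1 1 of 100 called 8576 (4661). With BAY in hypoxia the real split called 8087 genes and the highest of the others 2, and with 10 splits, of which 1 called as many, the splits are too few for a share under 0.05.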
